A study of Mus musculus with 4 samples.

How the data were processed

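RNA from mouse liver was measured on 4 Affymetrix MG_U74Av2 arrays, 2 of control mice (replicates 7 and 8) and 2 of hepatic reductase null mice (replicates 7 and 8). Per the labels' protocols, liver was taken directly after killing, total RNA was extracted with TRIzol and a column, and labelled cRNA was hybridised, stained and scanned. The labels also say that RNA of 3 animals per genotype was pooled for each of the experiments, while the titles of the control samples speak of a mouse, so it is left open whether an array holds a pool or an animal. The p-values rest on the spread between these samples, which was in part pooled over probe sets of similar signal. The number of arrays limits the precision, and no batch is given in the labels.

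The deposited values are the intensity of each probe set on a linear scale, computed with GCOS software from perfect match and mismatch probes and scaled to total chip fluorescence, per the labels. The software version and the target value are not given in the sources used here. The trimmed mean of the deposited signals (2% cut from each end) came to 100.1 on every array, and the median signal was 26.1 and 26.7 on the control arrays and 27.2 and 28.4 on the null arrays. Detection calls were not used here. The table held 12488 probe sets, of which 66 were the manufacturer's control probe sets and were left out of the comparison.

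Signals were not normalised again. They were floored at 7.1, the 25th percentile of all signals of the 4 arrays pooled, and converted to log2. Probe sets whose mean log2 signal lay above log2 of 16.8 (the 40th percentile) were tested, 7241 in all. Folds against a group lying at the floor on both arrays are given as lower bounds against the floor. A value near the floor is mostly background, so changes of dim genes are understated. Between 24.7% and 25.6% of the probe sets of an array lay at or below the floor.

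Names came from a probe-to-gene table of the platform, updated through gene identifiers to the GRCm38.p6 gene table, in which 10839 annotated probe sets were matched. Of the 12422 probe sets that are not controls, 10833 carried 1 gene symbol, 396 carried several and were not named, and 1193 are unnamed here. A gene with several tested probe sets was represented by the brightest, which gave 5510 genes. Probe sets whose names end in _f_at, _r_at, _s_at, _i_at or _g_at can also bind related transcripts, which leaves members of the cytochrome P450, glutathione transferase and acute phase families uncertain. The values of the brightest and the other tested probe sets disagreed in sign or in passing the threshold for some named genes, and the report says so where such a gene is called.

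Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with genotype as the only term. The fit drew the variance of each probe set toward that of probe sets of similar signal. This pooled part counted for 4.78 degrees of freedom, against 2 from the arrays themselves. P-values were adjusted by Benjamini-Hochberg over the 7241 probe sets, and 0.05 was the threshold. An exact permutation test of 2 arrays against 2 cannot go below a two-sided p of 0.333, so no such test is reported. Gene lists, 37 of genes and 12 of cell type markers, were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives except those said to be added. The 42 lists with at least 5 tested genes were tested with camera of limma at a preset correlation between genes of 0.01, which compares a list's genes with all other genes, and adjusted over the 42 lists. The lists share genes. Camera with an estimated correlation and fry, whose directional p asks whether a list's genes move one way on balance, were run beside it.

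Named genes were those set beforehand for this tissue, the 10 largest rises and falls among genes past the threshold with no overlap between the groups, up to 4 members of smallest p in each list, and any measured member of the lists of P450 enzymes, their electron donors, bile acid synthesis and cholesterol synthesis. Genes named outside this rule are said to be so.

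The steps were tested on simulated data. In 20 draws for the null against control comparison on 7241 probe sets, 200 probe sets per draw were changed, and the fit recovered 6.5% of those changed 1.5-fold, 28.2% of those changed 2-fold, 72.8% of those changed 4-fold and 82.7% of those changed 8-fold, with 4.9% of all calls false. The noise was drawn from the spread that the fit itself assumes, independently for each probe set. The 4.9% therefore checks the steps and need not hold on the real arrays. On 5510 genes, camera with the preset correlation called 100% of 100 lists of 15 genes shifted by 0.5 on the log2 scale and 1% of 400 unchanged lists. These genes were simulated without correlation, so the 1% need not hold for lists whose genes move together. In the 14 lists that passed on the real arrays, the estimated correlation ran from -0.08 (periportal hepatocyte genes) to 0.96 (pancreatic acinar markers). It was 0.43 for CAR and PXR targets, against the preset 0.01. Camera with an estimated correlation called 0% of the same shifted lists and fry 34%, although those genes were simulated without correlation, so with 4 arrays a list that misses the threshold there is not shown to be unchanged.

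The alternatives were no floor, a higher floor, a pseudocount in place of the floor, no filter or a stricter one, quantile normalisation, median centring, no intensity trend, the replicate number as a block, each array left out in turn, other set tests, the mean of a gene's probe sets, and a rule on fold alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.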

Results

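Liver gene expression was compared between control mice and hepatic reductase null mice, with 2 arrays per genotype. The reductase is taken here to be NADPH-cytochrome P450 oxidoreductase (Por), which passes electrons to the microsomal cytochrome P450 enzymes and which is deleted in hepatocytes in the known mouse line of this name. No probe set of the annotation used here names Por, so its level was not analysed here and the labels were not checked against it. Across all probe sets the Pearson correlation of the signals was 0.996 between the control arrays, 0.993 between the null arrays and 0.972 to 0.983 between genotypes, over probe sets, which are not independent replicates. The arrays of a genotype were not copies of each other. The SD of their log2 difference was 0.47 for the control pair and 0.55 for the null pair.

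Null liver had higher signals for the drug-inducible Cyp2b10, Cyp3a11 and Gstm3, for metallothioneins and for the macrophage genes Mpeg1 and Mmp12, and lower signals for Hal and Cyp7b1. Cyp2b10, the classical target of the nuclear receptor CAR, rose by 5.14 ± 0.55 on the log2 scale (SE, 35.2-fold), from a signal of 11.2 ± 11.5 (SD, n = 2) in control liver, where 1 of the 2 arrays lay below the floor, to 452.1 ± 263 (SD, n = 2). This fold depends on the floor and on each array, with a log2 change of 4.42 without control replicate 7 and 5.86 without control replicate 8, and the call ended without null replicate 7 (5.77, adjusted p = 0.0743) or null replicate 8 (4.51, adjusted p = 0.168). Metallothionein 2 (Mt2) rose 7.40-fold, from 109 ± 25.4 to 794 ± 78.1 (SD, n = 2 each), and Mt1 rose 5.19-fold, from 147 ± 54.7 to 735 ± 1.48. Cyp8b1, the sterol hydroxylase that sets the share of cholic acid among bile acids, rose 2.92-fold, from 1196 ± 324 to 3431 ± 111. Among named genes past the threshold the largest fall was that of Hal, the enzyme that begins histidine breakdown, which was 2.98-fold lower in null liver, at 268 ± 57.2 against 790.4 ± 22.3.

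**Figure D1:**
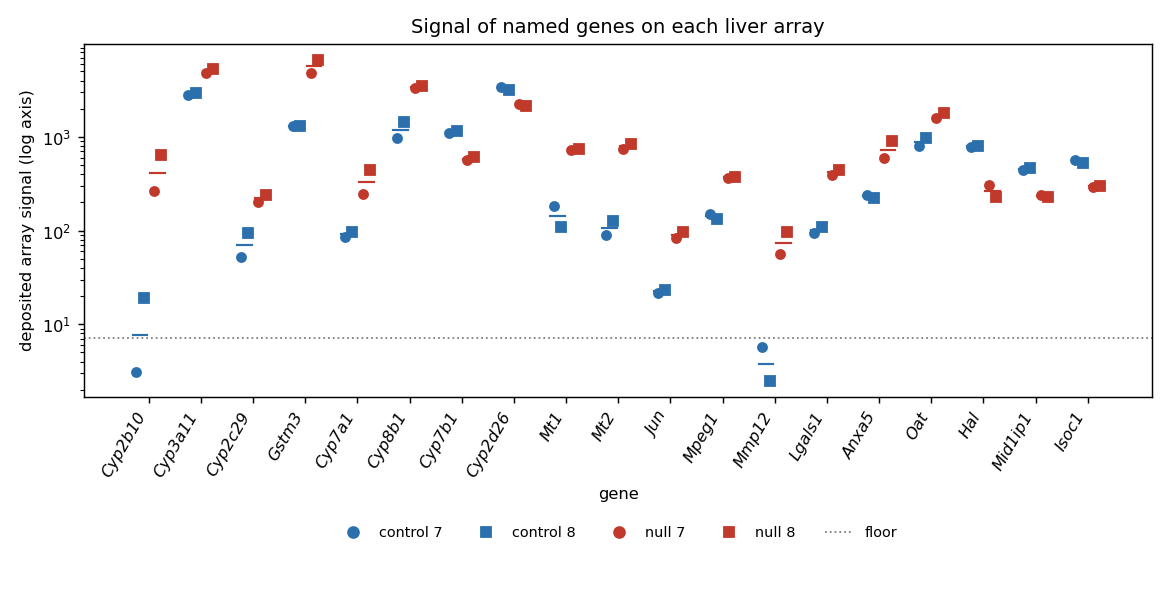
Deposited array signal (log axis) of 19 named genes on the 4 liver arrays, with control in blue, null in red, replicate 7 as circles, replicate 8 as squares, geometric group means as short bars and the floor as a dotted line. Cyp2b10 lay at 3.1 and 19.3 on the control arrays and at 266 and 638 on the null arrays, while the Hal signals were 775 and 806 against 309 and 228.

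Of 7241 probe sets tested, 22 were higher and 6 lower in null liver at an adjusted p under 0.05. They carried 18 genes that rose and 5 that fell, and 3 of the higher probe sets had no single gene name. The smallest adjusted p belonged to a probe set of Gstm3 (adjusted p = 0.000655), followed by Mt2 (0.00437) and Lgals1 (0.00676), with Cyp3a11 at 0.021, Cyp2b10 at 0.0253 and Cyp8b1 at 0.0261. Among the named genes Lgals1, a galectin, rose by 2.04 ± 0.15 (log2, SE), the transcription factor Jun by 2.01 ± 0.23, Anxa5, an annexin, by 1.65 ± 0.20 and Mmp12, the macrophage elastase, was at least 10.3-fold higher, since both of its control signals lay below the floor (adjusted p = 0.0377). The falls beside Hal were Mid1ip1, a regulator of lipogenesis, at -0.97 ± 0.12, Cyp7b1 at -0.94 ± 0.10, Isoc1 at -0.87 ± 0.11 and Cyp2d26 at -0.61 ± 0.08 (log2, SE). Another probe set of Mid1ip1 (-0.30) did not pass, nor did another of Mmp12 (at least 5.97-fold higher, with both control signals below the floor). Krt8, S100a10, Tmem176a, Entpd5 and Aqp8 also rose, by 0.89, 1.05, 0.83, 1.31 and 1.05, and are named outside the rule after their values were seen. At an unadjusted p under 0.05 in limma there were 446 higher and 468 lower probe sets, 914 in all. For both directions together 362.1 are expected by chance. Of the probe sets tested, 43.8% had null and control arrays that did not overlap, and chance gives 33.3% with 2 arrays against 2. Leaving out 1 array gave 10 to 13 higher and 0 to 4 lower probe sets, and of the 22 named genes that passed, only Gstm3 passed without each array in turn. The calls also ended without the filter on dim probe sets, with a floor at the 50th percentile and without an intensity trend, each of which gave 0 higher and 0 lower probe sets in limma.

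Gstm3, Cyp3a11 and Cyp2b10, which are induced through the xenobiotic receptors, rose in null liver. Of the 14 tested CAR and PXR targets, 3 rose, 0 fell and 11 did not pass over all probe sets, and 10 rose adjusted over the list alone. The list was higher in null liver by camera (adjusted p = 7.88e-11), with adjusted p = 0.59 with an estimated correlation and adjusted p = 0.163 by fry, and its median log2 change was 0.53. It stayed past the threshold without each array in turn (largest adjusted p = 1.79e-08). Gstm3, a glutathione transferase, rose by 2.11 ± 0.14 on its brightest probe set and by 3.53 on another, and Cyp3a11, the main PXR-inducible P450, rose by 0.81 ± 0.08 from an already high 2882 ± 130.4 (SD, n = 2). Both Gstm3 probe sets are of kinds (_f_at and _r_at) that can also bind related transcripts, so a share of related transferases in this rise stays open. Abcc3, a conjugate exporter of the sinusoidal membrane, was at 0.65 ± 0.09 (adjusted p = 0.0551) and Cyp2c29 at 1.64 ± 0.28 (adjusted p = 0.0803).

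The wider P450 list went both ways. Among 17 tested xenobiotic P450s of families 1 to 3, 2 rose, 1 fell and 14 did not pass, with 4 higher and 4 lower adjusted over the list alone, and the list did not pass by camera (adjusted p = 0.277). Cyp3a16 was at 1.74 ± 0.38 on a dim probe set, whereas Cyp2f2 was at -0.48 ± 0.07 and Cyp2d10 at -0.28 ± 0.06 (log2, SE). Cyp1a2 was at 0.28 ± 0.11 and Cyp2e1, the ethanol-inducible P450, at -0.10 ± 0.06. Of the 6 tested P450 electron donors other than Por, 0 passed in limma over all probe sets and 0 adjusted over the list alone. None of the 6 family 4 P450s passed over all probe sets, and 1 was lower adjusted over the list alone (Cyp4v3, -0.66 ± 0.10). Cyp4a10 was at 0.82 ± 0.50 and Cyp4a14 at 1.45 ± 0.81, with control signals that differed between the arrays (48.6 and 317.6 for Cyp4a14). Without control replicate 7 the value of Cyp4a10 was -0.02.

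Of the conjugating enzymes in the lists tested here, Gstm3 alone rose over all probe sets. Of 16 glutathione transferases 1 rose over all probe sets, with 4 higher and 1 lower adjusted over the list alone (list adjusted p = 0.168). Gstm1 was at 0.37 ± 0.06 and Gstm2 at 1.74 ± 0.30, both close in sequence to Gstm3, and other probe sets were at -0.11 for Gstm1 and 0.37 ± 0.26 for Gstm2. Of 10 glucuronosyl and sulfotransferases 0 passed in limma over all probe sets and 4 were higher adjusted over the list alone. That list was higher by camera (adjusted p = 0.0452), with adjusted p = 0.59 with an estimated correlation, and it did not pass without control replicate 8 (0.0994), null replicate 7 (0.0542) or null replicate 8 (0.122). Ugdh, which makes the sugar donor for glucuronidation, was at 0.63 ± 0.11 and Papss2, which makes the sulfate donor, at 0.56 ± 0.14. Of 21 NRF2 targets 1 rose, with 4 higher and 2 lower adjusted over the list alone (list adjusted p = 0.277). Gclc, of glutathione synthesis, was at -0.51 ± 0.11 and Gstp1 at -0.19 ± 0.06, the members lower adjusted over the list alone. Nqo1 (0.84 ± 0.34) and Hmox1, haem oxygenase (0.56 ± 0.18), did not pass there. Alas1, which starts haem synthesis, was at 0.29 ± 0.08 (adjusted p = 0.204).

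Bile acid enzymes changed in opposite directions. Of 10 tested genes 1 rose (Cyp8b1), 1 fell (Cyp7b1, of the alternative pathway) and 8 did not pass, with 2 higher and 3 lower adjusted over the list alone, and the list did not pass by camera (adjusted p = 0.861). Both tested probe sets of Cyp7b1 fell, the second by 1.11 on the log2 scale. Cyp7a1, the rate-limiting enzyme of the classical pathway, lay at 86.1 and 97.4 on the control arrays and at 243.9 and 441.7 on the null arrays, a log2 change of 1.84 ± 0.28 that missed the threshold (adjusted p = 0.0605). Nr0b2, a repressor of Cyp7a1 transcription, was at -1.91 ± 0.76 and did not pass (adjusted p = 0.365). Its signals were 100 and 91.2 on the control arrays, 64.4 on null replicate 7 and 10, near the floor, on null replicate 8.

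Of 17 tested cholesterol synthesis genes and SREBP2 targets 0 passed in limma over all probe sets and 6 were higher adjusted over the list alone, with 10 positive and 7 negative changes. The list was higher by camera (adjusted p = 0.00614), with adjusted p = 0.59 with an estimated correlation, and did not pass without null replicate 7 (0.36) or control replicate 8 (0.0774). Hmgcs1 was at 0.55 ± 0.12, Lss at 0.73 ± 0.23, Idi1 at 0.49 ± 0.15, Mvk at 0.69 ± 0.21 (0.14 on another probe set) and Cyp51 at 0.52 ± 0.21, while Sqle was at -0.07 ± 0.21 (log2, SE) and turned sign with the arrays left out. Fatty acid synthesis and desaturation did not pass as a list (adjusted p = 0.809), and of its 16 genes 0 passed in limma on their brightest probe set over all probe sets, with 2 higher and 2 lower adjusted over the list alone. Srebf1, the regulator of lipogenic genes, was at -0.94 ± 0.14 (adjusted p = 0.0551), while Scd1, Fasn, Pck1 and G6pc were within 0.12 of 0. A probe set of the stearoyl-CoA desaturase Scd2 rose by 1.95, and its brighter probe set was at 1.43 and did not pass. Of 34 PPAR-alpha targets and fatty acid oxidation genes 0 passed in limma over all probe sets and 3 were higher adjusted over the list alone, namely Aldh3a2 (0.94 ± 0.14), Pex11a (0.86 ± 0.15) and Crat (0.90 ± 0.16), of which Crat had another probe set at -0.25. The list was higher by camera (adjusted p = 0.00614), with adjusted p = 0.59 with an estimated correlation, and did not pass without control replicate 7 (0.167) or null replicate 7 (0.114). Cpt1a was at 0.18 ± 0.08, and Apoa4, an apolipoprotein, at 1.73 ± 0.24 (adjusted p = 0.0538).

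Metallothioneins and Jun rose in null liver. Of 18 metallothionein and acute stress genes 3 rose (Mt1, Mt2 and Jun), 0 fell and 15 did not pass, and 8 rose adjusted over the list alone. The list was higher by camera (adjusted p = 9.65e-06), with adjusted p = 0.59 with an estimated correlation, and it did not pass without null replicate 7 (adjusted p = 0.0542, mean log2 change 0.57 against 0.95 with all arrays). Atf3 was at 1.54 ± 0.30. Of 18 genes of endoplasmic reticulum stress 0 passed in limma over all probe sets and 3 were higher adjusted over the list alone (Hspa5 at 0.50 ± 0.10, Atf3 and Asns at 1.42 ± 0.35), with adjusted p = 0.0827 for the list. Of 20 acute phase proteins 0 passed in limma over all probe sets, with 3 higher and 5 lower adjusted over the list alone (list adjusted p = 0.682). Lcn2 was at 3.62 ± 0.68 (0.69 ± 0.59 on another probe set) and Orm2 at 1.62 ± 0.34, while Itih4 was at -0.58 ± 0.10 and the fibrinogen chain Fgg at -0.33 ± 0.07.

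Markers of macrophages and of stellate cells were higher as lists, while those of endothelial cells (adjusted p = 0.236), neutrophils (0.277) and B and plasma cells (0.353) did not pass by camera. Of 16 Kupffer cell and macrophage markers 1 rose (Mpeg1, by 1.38 ± 0.14), 0 fell and 15 did not pass, with 4 higher adjusted over the list alone. This list was higher by camera (adjusted p = 1.93e-05), with adjusted p = 0.59 with an estimated correlation, and Lyz2 was at 1.10 ± 0.21 and Cd14 at 0.87 ± 0.19. These are among its largest changes. The list's median was 0.29, with 14 positive and 2 negative changes. The mean was 0.22 for its 5 Kupffer cell markers and 0.52 for the 11 others. Of 14 stellate cell and fibroblast markers 0 passed in limma over all probe sets and 4 were higher adjusted over the list alone, and the list was higher by camera (adjusted p = 0.000786), with adjusted p = 0.59 with an estimated correlation. Col1a1 was at 1.81 ± 0.36 and Col3a1 at 1.31 ± 0.34. Both lists passed without each array in turn. Of 13 antigen presentation genes 0 passed in limma over all probe sets and 2 were higher adjusted over the list alone, Cd74 (0.45 ± 0.10) and H2-Aa (0.55 ± 0.15). That list was higher by camera (adjusted p = 0.0104), with adjusted p = 0.59 with an estimated correlation, and did not pass without null replicate 7 (0.271) or control replicate 8 (0.0642). Pancreatic acinar markers, which liver should lack, were higher by camera too (adjusted p = 0.0136, and adjusted p = 0.61 with an estimated correlation). Their signals were raised on null replicate 7, with Ctrb1 at 1307 against 58.0, 71.8 and 78.7 on the other arrays, and without that array the list's mean log2 change was -0.07 (adjusted p = 0.687).

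**Figure D2:**
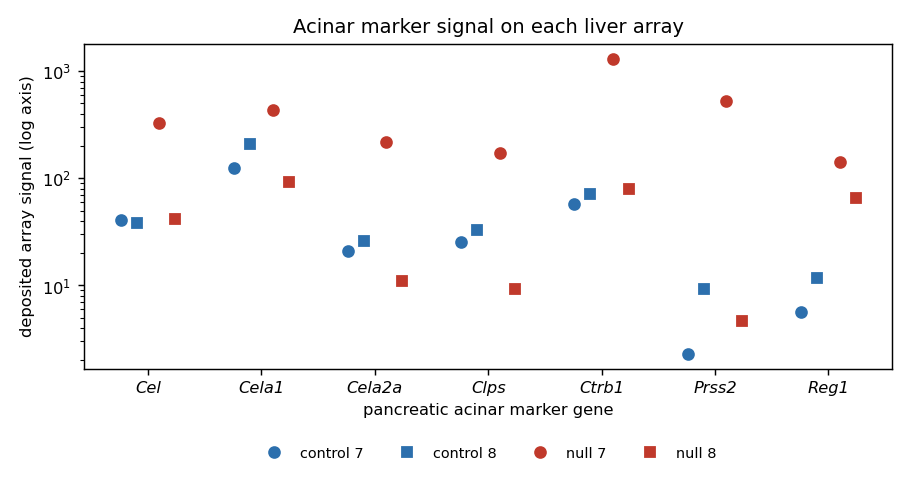
Deposited array signal (log axis) of the 7 tested pancreatic acinar marker genes on the 4 liver arrays, with control in blue, null in red, replicate 7 as circles and replicate 8 as squares. Each marker was highest on null replicate 7, where Ctrb1 reached 1307, and Reg1 was also raised on null replicate 8 (65.4 against 5.7 and 11.8 on the control arrays).

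**Figure D3:**
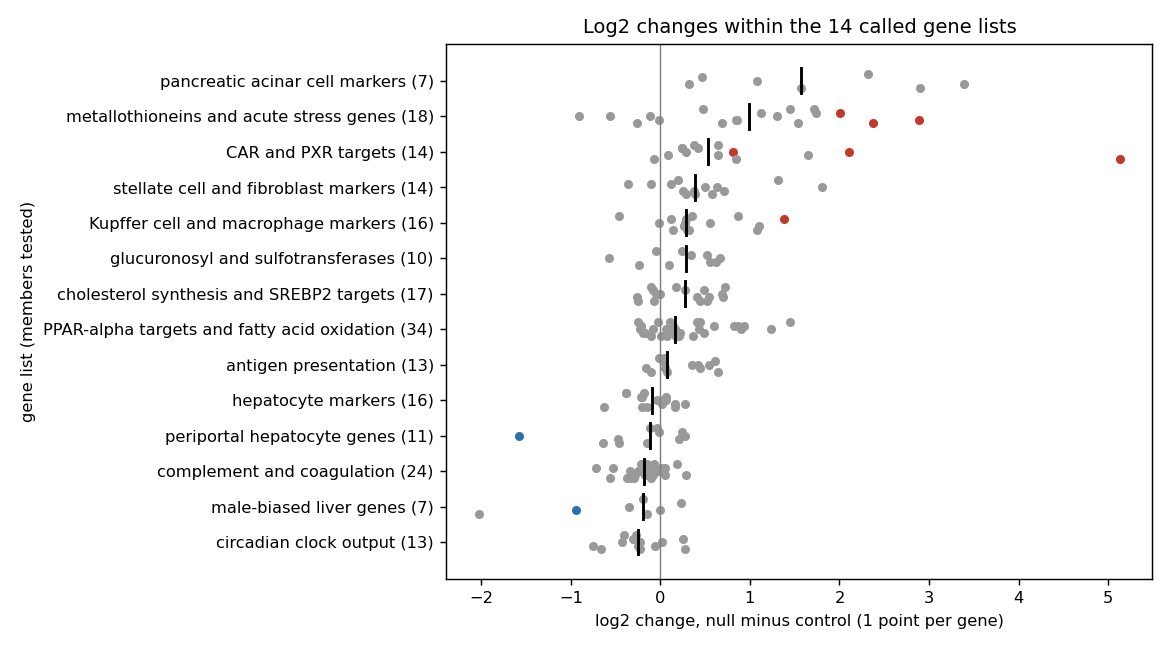
Log2 change (null minus control) of each tested gene in the 14 gene lists that passed by camera, with list medians as black bars, genes that rose in red, genes that fell in blue and genes that did not pass in grey. CAR and PXR targets had a median of 0.53 and reached 5.14 for Cyp2b10, while complement and coagulation genes had a median of -0.18.

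Several lists of hepatocyte genes were lower by camera. Of 24 tested complement and coagulation genes 0 passed in limma over all probe sets and 5 were lower adjusted over the list alone, and 19 of 24 had a negative change. The list was lower by camera (adjusted p = 5.32e-05), with adjusted p = 0.59 with an estimated correlation, and passed without each array in turn. Complement component C9 was at -0.72 ± 0.12, complement C5 (Hc) at -0.53 ± 0.09 and protein C (Proc) at -0.57 ± 0.10 (log2, SE). Of 11 periportal hepatocyte genes 1 fell (Hal), with 4 lower adjusted over the list alone, among them Cyp2f2 and Pigr (-0.47 ± 0.07). The list was lower by camera (adjusted p = 0.00947), with adjusted p = 0.59 with an estimated correlation, and did not pass without control replicate 8 (0.0642) or null replicate 7 (0.0542). Of 9 pericentral genes 1 rose, Oat (0.93 ± 0.12), and 2 were higher adjusted over the list alone (list adjusted p = 0.15). Of 24 urea cycle and amino acid genes 1 rose (Oat) and 1 fell (Hal), with 2 higher and 4 lower adjusted over the list alone (list adjusted p = 0.152).

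Among 7 male-biased liver genes 1 fell (Cyp7b1), with 4 lower adjusted over the list alone. The list was lower by camera (adjusted p = 0.00614), with adjusted p = 0.59 with an estimated correlation, and did not pass without control replicate 8 (0.0778). Hsd3b5, a steroid dehydrogenase of male liver, was at -2.03 ± 0.40, from 1401 and 1238 on the control arrays to 529 and 197 on the null arrays. Of 13 circadian output genes 0 passed in limma over all probe sets and 2 were lower adjusted over the list alone, Tef (-0.75 ± 0.16) and Bhlhe40 (-0.66 ± 0.16). That list was lower by camera (adjusted p = 0.0436), with adjusted p = 0.59 with an estimated correlation, and did not pass without control replicate 8 (0.0977), null replicate 7 (0.067) or null replicate 8 (0.122). Of 16 hepatocyte markers 0 passed in limma over all probe sets and 3 were lower adjusted over the list alone, among them Tdo2 (-0.38 ± 0.06) and Ttr (-0.63 ± 0.14). The marker list was lower by camera (adjusted p = 0.0426), with adjusted p = 0.59 with an estimated correlation, and did not pass without control replicate 7 (0.105), control replicate 8 (0.0875) or null replicate 8 (0.102).

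In all, 14 of the 42 tested lists passed by camera, 9 higher and 5 lower. With an estimated correlation 0 passed, with 1 at an unadjusted p under 0.05, and fry's directional test also passed 0, with 11 at an unadjusted p under 0.05 (smallest adjusted p = 0.089). Fry's mixed test asks whether a list's genes change in either direction, without comparing them with other genes. It passed 26 lists, among them bile acid synthesis (adjusted p = 0.0193), which camera did not call.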

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

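The combination of the higher floor with the stricter filter was chosen after seeing the data. The main counts were 22 probe sets higher, 6 lower and 14 gene lists. A floor at the 50th percentile gave 0 and 0 probe sets and 9 lists (in limma 459 higher and 496 lower at an unadjusted p under 0.05), no filter 0, 0 and 8 (566 and 642), and no intensity trend 0, 0 and 7 (407 and 340). Why the calls ended without the filter or the trend was not tested. The stricter filter gave 15 lower and quantile normalisation 12. The higher floor with the stricter filter gave 40 and 21, of which 21 and 6 were among the main calls. That floor therefore did not end the calls once more of the dim probe sets were left out. A change of 2-fold or more in all 4 array pairs, without a test, was met by 50 higher and 23 lower probe sets, of which 16 and 1 were among the calls. Camera with an estimated correlation and fry's directional test each gave 0 lists. Leaving out 1 array, with a lone array assumed to vary like the other group, gave 10 to 13 higher, 0 to 4 lower and 6 to 13 lists. Replicate numbers 7 and 8 occur in both genotypes, but no label ties them to a shared batch, and with the number as a block 37 probe sets were higher and 15 lower. Deviations of same-numbered arrays correlated at -0.03 over probe sets. That value compares 1 difference between arrays per genotype, so it cannot decide whether same-numbered arrays share an experiment.

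Of 89 genes followed 83 kept their direction under every alternative that gave them a value, as did 13 of the 14 lists. A gene whose null and control arrays do not overlap cannot change direction when 1 array is left out. Genes were partly named for such a gap or for a small p, so their kept direction is no separate support. With the stricter filter 84 of the genes and 13 of the lists had a value. Scd1 turned to 0.0169 with quantile normalisation. With 1 array left out Scd1 ran from -0.16 to 0.0645, Cyp4a10 from -0.0187 to 1.65, Sqle from -0.31 to 0.17, G6pc from -0.16 to 0.30, Pck1 from -0.31 to 0.0673, Fasn from -0.27 to 0.0331 and the acinar list from -0.069 to 3.51. The targeted gene has no value under any alternative, since it is unnamed here. Dim probe sets are limited by signal over background. The real split of the arrays called 28 probe sets and the other 2 splits 0 each (139 and 192 at an unadjusted p under 0.05 in limma), and 3 splits are too few for a share under 0.05. Each of the other splits puts 1 control and 1 null array in each group, so a genotype difference widens the spread within groups. Their counts are therefore no reference for chance.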

Other observations

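The tests of the acinar, cell type and 18S patterns below were chosen only after the results were seen, while the changes of single genes come from the planned comparison. Some members of lists that did not pass by camera or had too few genes to test had sizeable changes, and the 4 named here did not pass over all probe sets. Igfbp1, a secreted binding protein of insulin-like growth factors, was at 2.30 ± 0.40 (log2, SE), with signals of 62.2 and 164.5 on the control arrays and 527 and 469.8 on the null arrays. Hsd11b1, which regenerates active glucocorticoid in liver, was at -1.02 ± 0.20. The erythroid genes Alas2 (-0.64 ± 0.12) and Hba-a1 (-0.27 ± 0.06) were lower on both null arrays than on both control arrays.

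The null arrays differed from each other in some genes, named here after their values were seen. The immediate early gene Fos was at 260.7 on null replicate 7 and at 7.7 on null replicate 8, and Egr1 was at 326 and 113. Lcn2 was at 76.4 and 396 on its brightest probe set, and Saa2 at 892 and 2364.

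Acinar transcripts were high on null replicate 7. All 7 tested acinar markers had their highest signal on that array, with a median log2 change from the control mean of 3.22, while on null replicate 8 the median was -0.19, which argues against a response shared by both null livers. Pancreatic tissue taken along with that liver would give such a rise, but the 3.22 restates the pattern and is no separate test of that source. Reg1 stands apart, since it was at 142 and 65.4 on the null arrays against 5.7 and 11.8. Suppose pancreas supplied Reg1 and the other 6 markers in the same proportion on both null arrays. The other markers then lay below the signal needed on null replicate 8 by a median log2 of -3.08. That argues against pancreas of this proportion as the source of Reg1 there, while pancreas relatively richer in Reg1 is not covered. A response of Reg1 in null liver stays open.

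Macrophage and fibroblast markers were higher by camera and hepatocyte markers lower, each at adjusted p = 0.59 with an estimated correlation, and the hepatocyte list had 9 negative and 7 positive changes, a median of -0.09 and a call that ended without control replicate 7 (0.105), control replicate 8 (0.0875) or null replicate 8 (0.102). If a smaller share of hepatocytes raised all other cell types alike, these would move together, and macrophage markers exceeded endothelial markers by a mean of 0.27 (permutation p over genes = 0.143, two-sided), and the other macrophage markers exceeded the Kupffer cell markers by 0.30 (exact permutation p over genes = 0.242). Over 57 markers of 7 other cell types the mean changes did not differ past 0.05 either (permutation p over genes = 0.18). The erythroid markers Alas2 and Hba-a1, at a mean of -0.46, go against a rise of all other types alike, but they are 2 genes. Mean changes of the remaining types were all positive. They were 0.67 for T and NK cell markers, 0.48 for stellate cell and fibroblast markers and 0.43 for macrophage markers. Neutrophil markers were at 0.42, B and plasma cell markers at 0.28 and endothelial markers at 0.15. A smaller hepatocyte share and a change in macrophages therefore cannot be told apart here, genes are not independent replicates, and a response of the null liver itself stays open as untested.

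Control probe sets for 18S ribosomal RNA were lower on both null arrays, at 2374 and 1730 against 4722 and 4365 for the 3' probe set. Their median log2 change was -1.16, whereas no actin or Gapdh control probe set moved by more than 0.16, which argues against array scaling as the cause. More degraded RNA in the null samples would raise 3' over 5' ratios. The mean log2 change of those ratios was -0.0792, less than the gap of 0.16 within the null group, so degradation stays open, and no biological explanation was tested.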
